A study of Homo sapiens with 6 samples.

How the data were processed

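RNA of MDA-MB-231 cells was sequenced after transfection with 25 nM of a control ASO or a MANCR ASO, in 3 libraries each, 48 hours after transfection. Per the labels' protocols, libraries were made from total RNA with a stranded kit that removes ribosomal RNA. Per the submitters' processing notes, cutadapt 1.6, TopHat2 0.6, HTSeq 0.6, DESeq2 1.8.1 and R 3.2.0 were used with build hg38; their roles, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The authors deposited 1 table with a signal per gene and library, which its name calls normalized counts. Per the values, each column holds read counts divided by 1 size factor per library: every value in each library was a whole multiple of that library's step (100% of values, tolerance 0.01 reads), and the totals came to 26337196, 25445627 and 23574451 reads in controls 1 to 3 and 25282194, 23658684 and 23866607 in MANCR ASO libraries 1 to 3. The step of control 2 was 1.009, so near 1 that a separate check of the unit could not accept the recovery for that column; count tests below use its recovered reads all the same. The lowest mean of a gene was 2.45 normalized reads, so genes seen less often are not analysed here. A count of 3 reads corresponds to between 2.77 and 3.25 normalized reads.

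Gene symbols came from a name table for 18617 of 18780 identifiers, and positions, gene types, transcript lengths and sequences from GENCODE 29 on GRCh38 for 18716, of which 16757 had the same version. Before averaging, libraries were compared pairwise over genes with 50 to 300 reads in the pair. MANCR ASO libraries 1 and 2 gave a robust SD of 0.38 in units of counting noise, against 1.4 to 2.45 for the other pairs within a group. The limit of that check was set after its values were seen. Between these libraries, 359 of 1713 pseudogenes (20.96%) and 15 of 12106 protein-coding genes (0.12%) with at least 50 reads differed by 1.5-fold and 3 units of counting noise. Their mean was used as 1 sample, so that 3 controls were compared with 2 MANCR ASO samples with 3 residual degrees of freedom. The design fixed beforehand had 3 against 3; it is given as an alternative, and the change was made from this check before gene counts or list tests were run.

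The test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized value + 1) over 17103 genes with a mean of at least 10 over the 6 libraries, two-sided, with Benjamini-Hochberg adjusted p below 0.05. Fold changes are on that scale, which understates those of low genes. Given means are arithmetic means of normalized reads and SE is that of the moderated fit. The genes named were, by a rule set in advance, MANCR, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50, a symbol that is not clone-based and no overlap between the libraries of both groups, and the 3 members of smallest p from each of 29 gene lists. The lists and this rule were fixed before the data were examined. Some single genes that this rule would name are not reported here. Further list members named as examples were chosen after their values were seen. The lists were tested by camera with a preset correlation of 0.01, adjusted over the 29 lists, with at least 5 tested members each. Of the lists, 15 passed, 6 higher and 9 lower. With a correlation estimated from the data 0 passed (1 at an unadjusted p below 0.05), and fry, which asks whether the genes of a list move one way without comparing them with other genes, gave 1, the epithelial genes. The test was checked on simulated counts with the means and dispersions of the 5 samples over 17103 genes. In these counts 200 genes were changed and genes varied independently, without the shared differences between libraries seen in the data. With limma-trend 2 of 67 genes changed 1.5-fold, 31 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, and 5 of 104 calls were false; edgeR called the same numbers, and DESeq2 made 28 false calls among 148.

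Alternatives planned in advance were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, TMM, quantile normalization, limma without the trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads (833 and 1975 genes changed), a replicate block, each library left out, adjusted p below 0.01 and 0.1, and a 1.5-fold limit. The block was fitted on the 6 libraries. The 3 against 3 fit, which was the design fixed beforehand, was kept as an alternative. Alternatives added after seeing the data were leaving out MANCR ASO libraries 1 and 2 together and a term for the set of libraries. Removal of each library's trend on transcript length and GC content (splines with 4 degrees of freedom) was also added then. The sets (control 1 with MANCR ASO libraries 1 and 2, and controls 2 and 3 with MANCR ASO library 3) were read from the data and not from a label. Where a library left an arm with 1 sample, that sample was assumed to vary like the others. Genomic span is the distance from the first to the last annotated base of a gene. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.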

Results

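MDA-MB-231 is a triple negative breast adenocarcinoma line derived from a metastatic site. Cells were transfected with 25 nM of an antisense oligonucleotide (ASO) against the long non-coding RNA MANCR, or with 25 nM of a negative control ASO, and total RNA was taken 48 hours later and sequenced after removal of ribosomal RNA. The series title names the cell cycle as the process of interest, and the design compares transcripts after a MANCR ASO and a control ASO. The samples hold no other ASO against MANCR and no rescue. For transcripts other than MANCR, effects of its loss therefore cannot be told apart from other effects of this oligonucleotide. There were 3 libraries per group, and each held between 23574451 and 26337196 gene-assigned reads over 18780 genes. MANCR ASO libraries 1 and 2 differed by less than the sampling noise: the median chi-square per gene was 0.07, against 0.45 expected from counting alone and between 0.9 and 2.83 for the other pairs of libraries within a group. Independently drawn reads would differ at least by counting noise, so MANCR ASO libraries 1 and 2 are not independent of each other. They were therefore averaged and counted as 1 sample, called MANCR sample 1/2 here, which leaves 3 control samples against 2 MANCR ASO samples. Nothing in the labels says that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

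MANCR (ENSG00000231298.6, annotated as a lincRNA on chromosome 10, 4650185 to 4678154, minus strand, GRCh38) was nearly lost after the MANCR ASO. Its normalized read count was 1141.7 ± 27.8 (SD, n = 3) in the controls and 38.8 ± 23.4 (SD, n = 2) in the MANCR ASO samples, which is 3.4% of the control mean. The 3 MANCR ASO libraries held 24, 23 and 53 MANCR reads, and the 3 control libraries 1186, 1114 and 1084. The log2 fold change was −4.98 ± 0.34 (SE), with an adjusted p of 0.00332 by limma-trend.

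Among 17103 genes tested by limma-trend, 863 changed at an adjusted p below 0.05, of which 286 rose and 577 fell. After MANCR, the falls of largest size among the genes named by the fixed rule were those of CAMKMT, a calmodulin methyltransferase (log2 fold change −4.41 ± 0.37 SE, with 3 reads in MANCR library 3), CENPP, a centromere protein (−3.76 ± 0.20), the non-coding LINC01278 (−3.19 ± 0.31), CCDC146 (−3.11 ± 0.45) and XPO7, a nuclear export receptor (−3.10 ± 0.15). XPO7 went from 2371.9 ± 145.3 (SD, n = 3) normalized reads to 248.4 in MANCR sample 1/2 and 304.9 in MANCR library 3. The others of the 12 were GPC6, F13A1, THSD4, NALF1, BMERB1, IMMP2L and CAMK1D, with log2 fold changes between −3.07 and −2.83. The 12 rises were led by LCN2, a secreted siderophore-binding protein (6.19 ± 0.73), which went from 5.2 ± 2.8 (SD, n = 3) to 907.2 and 182.8 normalized reads. LAMP3 (3.26 ± 0.55), the tight junction gene TJP3 (2.96 ± 0.36), the transglutaminase TGM1 (2.87 ± 0.55), MAP1A (2.68 ± 0.42) and SPX (2.58 ± 0.52) followed. MAL2, SMPDL3B, GPNMB, EPPK1, S100P and the pro-apoptotic BIK rose by log2 values between 2.42 and 2.52. The count of changed genes was 307 without control 1, 87 without control 2 and 24 without control 3. At an unadjusted p below 0.05 by limma, 3926, 3117 and 2713 genes differed in these fits, against 4163 over the 5 samples. The count of changed genes also fell without MANCR sample 1/2 and rose without MANCR library 3. It moved less without MANCR ASO library 1 (682) or 2 (979) alone, which leaves the other of the pair. Among 104 named genes other than MANCR, 62 passed, and 28, 44 and 58 of these no longer did without controls 1, 2 and 3, 45 without MANCR sample 1/2 and 2 without MANCR library 3. With the 6 libraries taken as 3 against 3 it was 3441, of which 860 were among the 863.

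**Figure D1:**
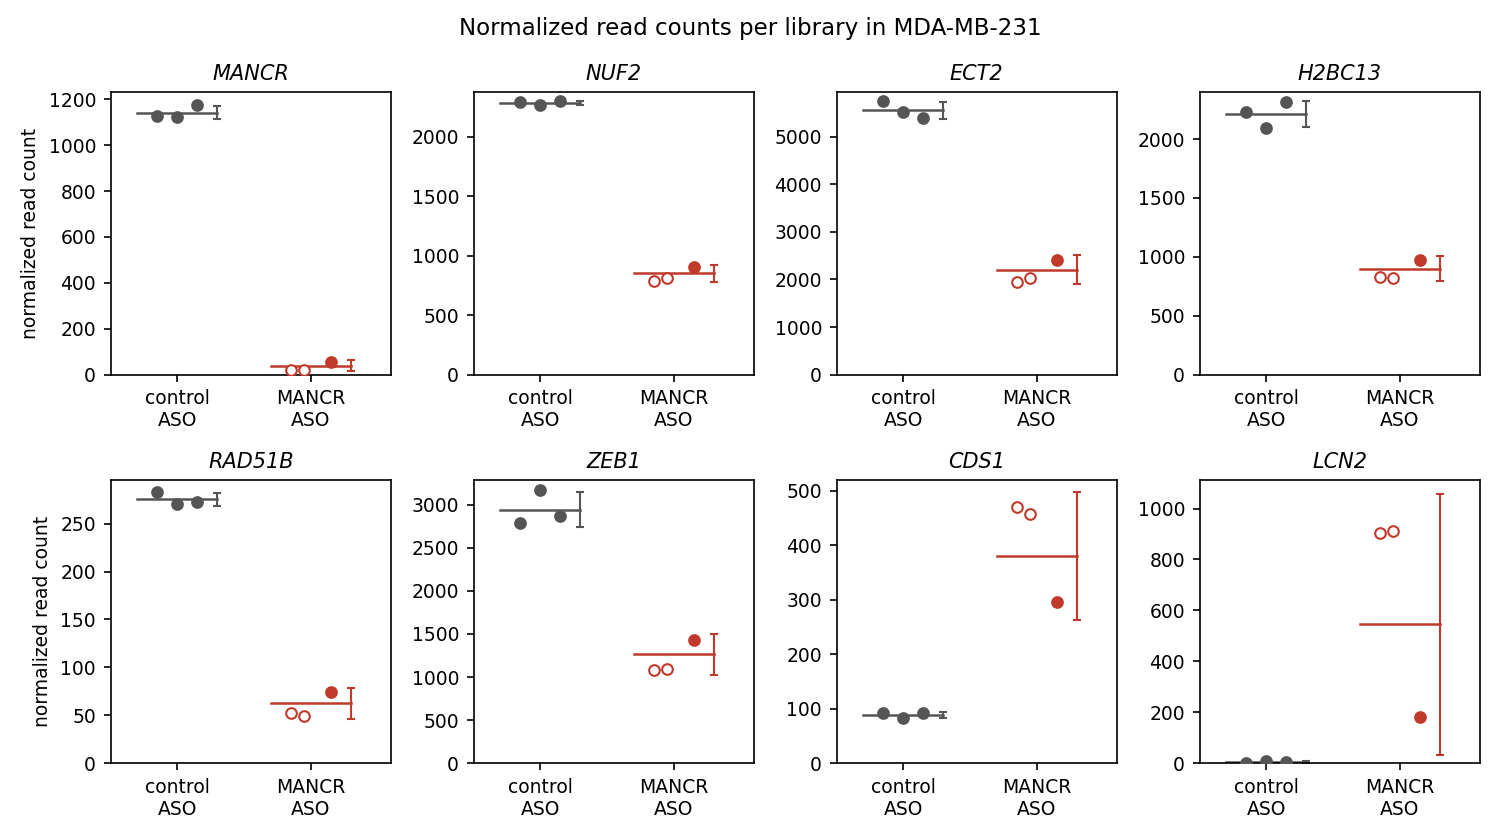
Normalized read counts (vertical axes, each starting at 0) of 8 genes in the 3 control ASO libraries (grey) and the 3 MANCR ASO libraries (red); open circles are MANCR ASO libraries 1 and 2, which count as 1 sample, horizontal lines are group means and bars are SD over 3 control and 2 MANCR ASO samples. Each MANCR ASO library lies below the controls for MANCR, NUF2, ECT2, H2BC13, RAD51B and ZEB1 and above them for CDS1 and LCN2.

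Cell cycle genes were lower after the MANCR ASO. Of 71 G2/M and mitosis genes, 20 fell and 0 rose over all genes, 63 fell when adjusted over the list alone, and 71 of 71 had a log2 fold change below 0, with a median of −0.69. NUF2, a kinetochore component, fell (log2 fold change −1.42 ± 0.12 SE) from 2283.6 ± 15.6 (SD, n = 3) to 801.5 and 902.3 normalized reads. ECT2, a GTPase exchange factor needed for cytokinesis (−1.34 ± 0.13), and the mitotic motor KIF18A (−0.73 ± 0.12) fell. The mitotic kinase CDK1 (−0.59 ± 0.12), its cyclin CCNB1 (−0.87 ± 0.19) and the centromeric histone CENPA (−0.92 ± 0.15) also fell. Of 50 S phase genes, 7 fell (30 adjusted over the list alone), with a median of −0.45; POLA1, the catalytic subunit of DNA polymerase alpha (−1.44 ± 0.17), the chromatin remodeller HELLS (−0.98 ± 0.14) and the ubiquitin ligase adaptor DTL (−0.93 ± 0.12) were among them. Of 34 cytokinesis and abscission genes, 5 fell (ECT2, RACGAP1, KIF14, CEP55 and BIRC5) and 1 rose, the abscission gene CHMP4C (1.17 ± 0.22). Adjusted over the list alone, 12 fell and 1 rose, and the median was −0.24. ECT2, RACGAP1, KIF14 and BIRC5 are also members of the G2/M and mitosis list, as are ANLN, PRC1, CIT, KIF23, KIF20A, AURKB, CDCA8 and PLK1. The cytokinesis result is therefore not independent of the mitosis result. By camera with a preset correlation of 0.01 the adjusted p was 5e-26 for G2/M and mitosis, 4.45e-15 for S phase and 0.00138 for cytokinesis. Each of these calls was lost with adjusted p = 0.722 with an estimated correlation. Without control 1, 2 or 3 the number of G2/M and mitosis genes that fell was 2, 2 and 0, without MANCR sample 1/2 it was 2, and without MANCR library 3 it was 52; in these limma fits between 51 and 67 members were lower at an unadjusted p below 0.05. The S phase count was 3, 1, 0, 0 and 14 in the same fits, with 21 to 34 members lower at an unadjusted p below 0.05, and the cytokinesis count of fallers 1, 1, 0, 1 and 12, with 10 to 17. CHMP4C passed in the fit without MANCR library 3 and in none of the other 4.

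Replication-dependent histone genes had the lowest median log2 fold change among the fixed lists. Of 35 tested members, 29 fell over all genes, 34 fell when adjusted over the list alone, and 35 had a log2 fold change below 0, with a median of −0.95 (camera adjusted p 2.27e-26, and adjusted p = 0.722 with an estimated correlation). H2BC13 (−1.30 ± 0.13 SE), H2BC12 (−1.15 ± 0.14) and H2AC14 (−1.14 ± 0.13) had the smallest p. Members of this family are near copies of each other, so single members are uncertain where reads could be split between them. Leaving out controls 1, 2 and 3, MANCR sample 1/2 or MANCR library 3 left 19, 8, 0, 1 and 28 members that fell by limma, with 34 or 35 of them lower at an unadjusted p below 0.05.

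Of 47 DNA double-strand break repair genes, 4 fell and 0 rose, 14 fell when adjusted over the list alone, and the median was −0.37 (camera adjusted p 6.47e-06, and adjusted p = 0.722 with an estimated correlation). These were the recombination gene RAD51B (−2.14 ± 0.22), the Fanconi anaemia gene FANCB (−1.81 ± 0.21), BARD1 (−0.76 ± 0.13) and the damage kinase ATM (−0.73 ± 0.12). Without controls 1, 2 and 3 the number was 2, 2 and 0, and without MANCR sample 1/2 it was 2; 12 to 22 members were lower at an unadjusted p below 0.05 in these limma fits. Of 28 p53 target genes, PHLDA3 rose (0.78 ± 0.16), 1 rose when adjusted over the list alone, and the median was 0.23; the camera adjusted p was 0.0128, it was 0.403 without MANCR sample 1/2, and adjusted p = 0.722 with an estimated correlation. FAS (1.06 ± 0.27) did not pass. Without control 1, 2 or 3 or MANCR sample 1/2, 0 p53 targets rose by limma, with 3 to 8 higher at an unadjusted p below 0.05, and without MANCR library 3, 4 rose and 1 fell; edgeR gave 1 and DESeq2 4. Of 20 cyclin-dependent kinase inhibitors and G1 regulators, 0 passed by limma-trend, over all genes or over the list alone. At an unadjusted p below 0.05, 2 were higher and 6 lower, edgeR gave 0 and DESeq2 gave 2 higher and 1 lower. CDKN1A had a log2 fold change of 0.71 ± 0.21, CDK2 of −0.64 ± 0.14 and RBL1 of −0.41 ± 0.13. The camera adjusted p of that list was 0.137, and without MANCR library 3, 2 members rose and 3 fell.

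**Figure D2:**
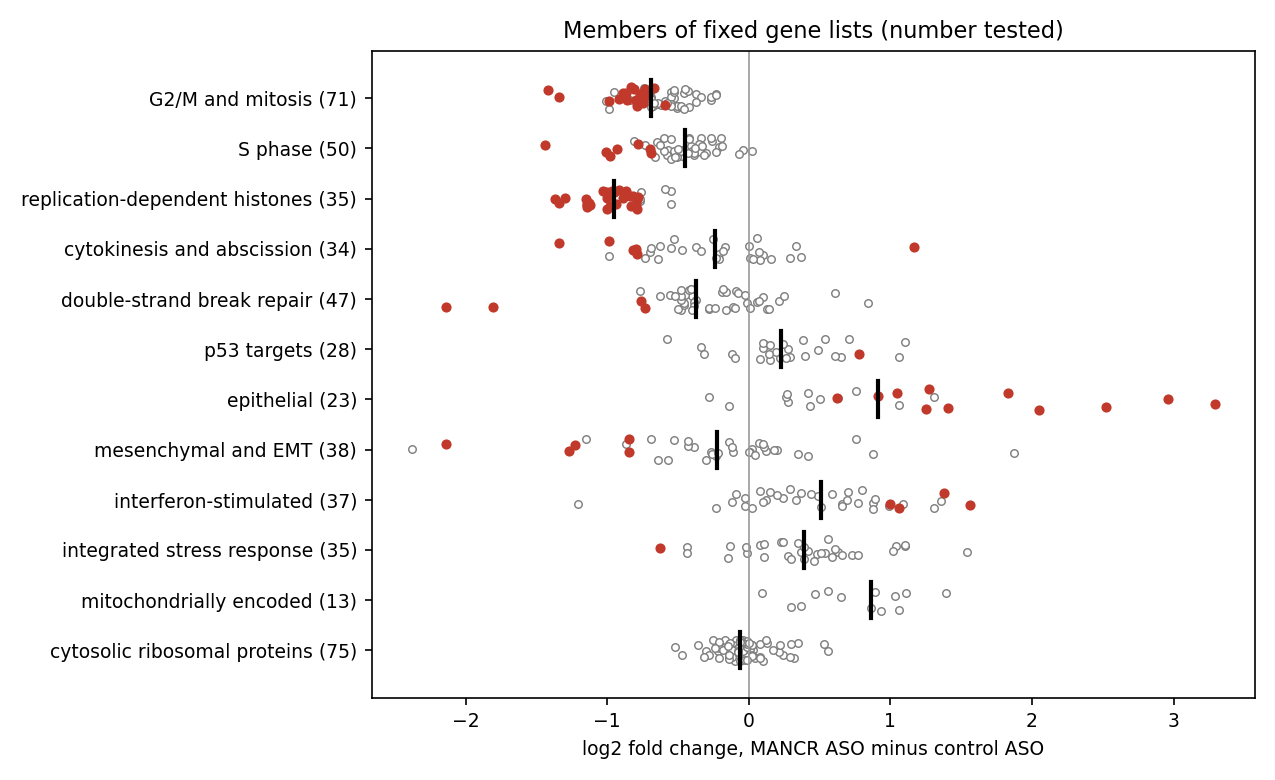
Log2 fold change, MANCR ASO minus control ASO (horizontal axis), of each tested member of 12 fixed gene lists, with the number tested in parentheses; red points passed an adjusted p of 0.05 over all genes, open points did not, and black bars are list medians. Of the points in the histone row, 35 of 35 lie below 0, and the epithelial row has a median of 0.91.

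Epithelial genes rose. Of 23 tested, 11 rose and 0 fell, 14 rose when adjusted over the list alone, and the median log2 fold change was 0.91. The camera adjusted p was 3.09e-10, with adjusted p = 0.155 with an estimated correlation, and by fry the adjusted p was 0.00548. CDS1 went from 89.0 ± 5.4 (SD, n = 3) to 463.3 and 296.6 normalized reads (2.05 ± 0.23 SE), the epithelial splicing regulator ESRP2 rose by 1.83 ± 0.24, and the tight junction gene TJP3 by 2.96 ± 0.36. E-cadherin (CDH1, 1.41 ± 0.26), OCLN (1.05 ± 0.16) and ESRP1 (3.29 ± 0.52) also rose. Of 38 mesenchymal genes, 5 fell and 0 rose; adjusted over the list alone, 8 fell and 1 rose. Among these were the transcriptional repressor ZEB1 (−1.23 ± 0.15), the actin-binding CALD1 (−1.27 ± 0.18), the matrix protein TGFBI (−2.14 ± 0.37) and the urokinase PLAU (−0.85 ± 0.15). The mesenchymal median was −0.22 (camera adjusted p 0.0376, and adjusted p = 0.88 with an estimated correlation), and that call was lost without control 2 (0.14), control 3 (0.0507) or MANCR sample 1/2 (0.406), with quantile normalization (0.109), at a mean of at least 50 (0.0733) and without the mean-variance trend (0.0629). Of 14 luminal breast markers, 3 rose and 1 fell, and KRT8 (0.62 ± 0.12), ERBB3 (1.03 ± 0.20) and GREB1 (1.55 ± 0.26) were those that rose; adjusted over the list alone, 4 rose and 3 fell, and the camera adjusted p was 0.307. Of 27 YAP/TAZ targets, TEAD1 (−1.34 ± 0.21), RBMS3 (−1.26 ± 0.22) and NT5E (−1.08 ± 0.23) fell and WWC1 (0.65 ± 0.14) rose; adjusted over the list alone, 3 fell and 6 rose. The YAP/TAZ median was 0.00 and the mean −0.06, while camera gave the direction as higher (adjusted p 0.949). Without control 3 or MANCR sample 1/2, 0 luminal and 0 YAP/TAZ members passed by limma, with 6 to 9 at an unadjusted p below 0.05; without control 1, 1 luminal and 1 YAP/TAZ member fell and 0 rose, and without control 2, 1 YAP/TAZ member rose and 0 luminal members passed. Without MANCR library 3, 2 luminal members rose and 4 fell, which turns the balance, and 3 YAP/TAZ members rose and 3 fell. The epithelial count was 4, 1 and 0 without controls 1, 2 and 3, 1 without MANCR sample 1/2 and 9 without MANCR library 3, with 12 to 16 members higher at an unadjusted p below 0.05 by limma. The mesenchymal count was 2, 0, 0, 0 and 10 in the same fits, with 8 to 13 members lower at an unadjusted p below 0.05.

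Of 37 interferon-stimulated genes, 4 rose and 0 fell: the exonuclease ISG20 (1.56 ± 0.31), OASL (1.38 ± 0.30), the ubiquitin ligase HERC5 (1.06 ± 0.21) and the transcription factor IRF7, which went from 640.4 ± 118.5 (SD, n = 3) to 1496.7 and 1080.9 normalized reads. Adjusted over the list alone, 14 rose and 1 fell, and the median was 0.51 (camera adjusted p 8.08e-07, and adjusted p = 0.722 with an estimated correlation). The number that rose was 1, 0 and 0 without controls 1, 2 and 3, 0 without MANCR sample 1/2 and 15 without MANCR library 3, and 1 fell without control 1 and 1 without MANCR library 3, with 12 to 22 higher at an unadjusted p below 0.05 by limma. Of 35 integrated stress response genes, VEGFA fell (−0.63 ± 0.14) and 0 rose; adjusted over the list alone, 2 rose and 1 fell, and the median was 0.39 (camera adjusted p 0.00358, and adjusted p = 0.88 with an estimated correlation). That call was lost without MANCR sample 1/2 (0.487), while 11 members rose without MANCR library 3. NUPR1 (1.54 ± 0.37) and WARS1 (0.77 ± 0.19) did not pass. For integrated stress, 9 members were higher at an unadjusted p below 0.05 by limma, and 0 rose by edgeR and 6 by DESeq2. VEGFA, the vascular growth factor, did not pass in these lists without any 1 of the 3 controls, MANCR sample 1/2 or MANCR library 3.

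Of 31 immediate early genes, FOSL2 (0.64 ± 0.12) and the mRNA decay factor ZFP36 (1.04 ± 0.18) rose, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.126, but 0.0246 without control 2 and 0.0308 without MANCR library 3). Of 24 NRF2 targets, FTH1 rose (1.37 ± 0.21), which is uncertain because it shares reads with processed pseudogenes; 1 rose when adjusted over the list alone (camera adjusted p 0.329, but 0.0363 without control 1). Of 26 unfolded protein response genes, ATF6 fell (−0.73 ± 0.13), 1 when adjusted over the list alone (camera adjusted p 0.751). Of 18 heat shock genes, 0 passed by limma-trend over all genes or over the list alone, 0 at an unadjusted p below 0.05, and 0 by edgeR or DESeq2 (camera adjusted p 0.476, but 0.0363 without control 1). Of 26 NF-kB and cytokine genes, 0 passed by limma-trend, over all genes or over the list alone. At an unadjusted p below 0.05, 1 was higher and 5 lower, and edgeR gave 0 and DESeq2 3 lower (camera adjusted p 0.307, but 0.0231 without control 3 and 0.0403 without MANCR sample 1/2, both lower), while without MANCR library 3, 2 rose and 0 fell. Of 30 apoptosis regulators, BIK rose (2.42 ± 0.33), with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p 0.821). Of 33 lysosome and autophagy genes, LAMP2 fell (−0.64 ± 0.12), 1 when adjusted over the list alone (camera adjusted p 0.821). Without control 3 or MANCR sample 1/2, 0 members of the immediate early, NRF2, unfolded protein response, apoptosis and lysosome lists passed by limma, without control 1, 1 apoptosis member rose and 0 of the others passed, and without control 2, 1 immediate early member rose and 0 of the others passed. Each of these lists had 2 to 12 members at an unadjusted p below 0.05 in those fits. Without MANCR library 3, more members of each of these lists passed than over the 5 samples. DESeq2 gave 5 higher and 1 lower for immediate early genes, and 3 and 2 for NRF2 and for the unfolded protein response. It gave 3 and 1 for apoptosis and 3 and 2 for lysosome genes.

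Among metabolic and translation lists, the 13 mitochondrially encoded genes had a median log2 fold change of 0.86 and 13 of 13 lay above 0, yet 0 passed by limma-trend over all genes; adjusted over the list alone, 3 rose. At an unadjusted p below 0.05, 5 were higher, and edgeR gave 0 and DESeq2 5. MT-ND2 had 1.03 ± 0.26 and MT-ND5 0.65 ± 0.15. Samples within a group also parted on these genes. The list median was −0.71 for control 1 minus controls 2 and 3, and −0.77 for MANCR sample 1/2 minus MANCR library 3. Without MANCR sample 1/2, 1 rose over all genes. The camera adjusted p was 0.00065, lost without MANCR library 3 (0.0819), and adjusted p = 0.722 with an estimated correlation. With the library set, which was read from the same values, as a term, 11 of 13 passed as higher by limma (camera adjusted p 6.99e-10). Mitochondrial ribosomal RNA took 0.027% of reads in control 1, 0.52% and 0.484% in controls 2 and 3, 0.514% and 0.509% in MANCR ASO libraries 1 and 2, and 1.996% in MANCR ASO library 3. Of 56 nuclear oxidative phosphorylation genes, the complex I gene NDUFA10 fell (−1.08 ± 0.20) but did not pass without any 1 of the controls or MANCR sample 1/2; 1 fell when adjusted over the list alone, with a median of −0.15 (camera adjusted p 0.0157, lost without control 1 at 0.232 and without MANCR library 3 at 0.113, with quantile normalization at 0.389, by DESeq2 at 0.0631 and with length and GC removed at 0.107, and adjusted p = 0.88 with an estimated correlation). Of 35 hypoxia and glycolysis genes, VEGFA fell, 0 when adjusted over the list alone, where 3 were higher and 10 lower at an unadjusted p below 0.05. By limma 11 fell without MANCR library 3, and 0 passed without any 1 of the 3 controls or MANCR sample 1/2; edgeR gave 0 and DESeq2 1 higher and 4 lower. The hypoxia median was −0.28 (camera adjusted p 0.0255, lost without control 2 at 0.0626 and without MANCR sample 1/2 at 0.709, with quantile normalization at 0.124, by DESeq2 at 0.0631 and at a mean of at least 50 at 0.0659, and adjusted p = 0.88 with an estimated correlation).

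Of 30 cholesterol biosynthesis genes, 0 passed by limma-trend over all genes or over the list alone, while 1 was higher and 7 lower at an unadjusted p below 0.05, edgeR gave 0 and DESeq2 gave 1 in each direction. The median was −0.36 (camera adjusted p 0.00717, and adjusted p = 0.88 with an estimated correlation), and the direction turned without MANCR sample 1/2 (camera adjusted p 0.755); the call was lost by DESeq2 (0.0621), and without MANCR library 3, 15 members fell. Of 40 MYC and nucleolar ribosome biogenesis genes, 0 passed by limma-trend over all genes or over the list alone, 4 were higher at an unadjusted p below 0.05, and edgeR gave 0 and DESeq2 1. The MYC list had a median of 0.10 (camera adjusted p 0.0379, and adjusted p = 0.893 with an estimated correlation), lost without control 2 (0.395) or control 3 (0.1), with the library set as a term (0.168), without a filter (0.0533), without the mean-variance trend (0.0827) and by DESeq2 (0.0631), and its direction turned without MANCR sample 1/2 (0.905). Of 75 cytosolic ribosomal protein genes, 0 passed by limma-trend over all genes or over the list alone; 1 was higher and 3 lower at an unadjusted p below 0.05, edgeR gave 0 and DESeq2 1. The ribosomal median was −0.06 (camera adjusted p 0.324, but 0.00419 without MANCR sample 1/2 and 0.0391 with the library set as a term).

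Around MANCR on 10p15, 23 genes were tested. MANCR and the aldo-keto reductase AKR1E2 (−1.23 ± 0.22) fell, 4 fell when adjusted over the list alone, and the median was −0.07 (camera adjusted p 0.0966, but 0.00713 by DESeq2). Without any 1 of the controls or MANCR sample 1/2, 1 member fell, and without MANCR library 3, 5 did. PFKP, in the same region, had −0.88 ± 0.21 and did not pass. Markers of other cells were few: 10 of 20 leukocyte markers were tested, 0 passed by limma-trend over all genes and 1 was higher when adjusted over the list alone (camera adjusted p 0.821), with 2 higher and 2 lower at an unadjusted p below 0.05, 0 by edgeR, 1 higher by DESeq2 and 1 lower without MANCR library 3. Of 5 tested fibroblast and endothelial markers, the endothelial adhesion gene PECAM1 fell (−1.50 ± 0.26) but did not pass without control 2, control 3 or MANCR sample 1/2, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p 0.935).

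The libraries also differed along an axis other than the ASO, which was read from the data and which no label names. Control 1 departed from controls 2 and 3 in the way MANCR sample 1/2 departed from MANCR library 3, with a correlation of 0.55 across 13503 genes, which are not independent replicates. Taken apart on that axis, MANCR sample 1/2 minus control 1 and MANCR library 3 minus controls 2 and 3 share no library. Which samples form a set was chosen from the same values, so agreement of these differences is not independent replication. Across the same genes these differences correlated with Pearson's r 0.8 and Spearman's rho 0.75, and 77.6% of genes had the same sign. Past 2-fold were 1477 genes in the first set and 448 in the second. More than 2-fold lower in both sets were 228 genes, more than 2-fold higher in both were 159, and 3 differed 2-fold in opposite directions. The G2/M and mitosis median was −0.92 in the first set and −0.45 in the second, the histone median −1.15 and −0.83, and the epithelial median 1.15 and 0.82. The S phase median was −0.61 and −0.36, the cytokinesis median −0.42 and −0.17, the repair median −0.39 and −0.26, the interferon median 0.68 and 0.26, the mesenchymal median −0.12 and −0.15 and the mitochondrially encoded median 0.90 and 0.99. Other lists called by camera lay near 0 in the second set: integrated stress response at 0.78 and 0.07, p53 targets at 0.44 and 0.08, cholesterol at −0.58 and −0.09, hypoxia at −0.46 and −0.08, nuclear oxidative phosphorylation at −0.27 and −0.07, and MYC at 0.11 and 0.02. With the set as a term in limma, 4053 genes changed, among them all 863. The set was read from these same values, so p-values with this term may be too small and the calls too many. Lists with 0 calls over the 5 samples without that term then had some. Besides the mitochondrial genes these were 9 cholesterol genes lower and 2 higher, 6 cyclin-dependent kinase inhibitors and G1 regulators lower and 3 higher, 7 MYC and nucleolar genes higher and 6 ribosomal protein genes lower. They also held 5 NF-kB and cytokine genes lower and 1 higher, 1 heat shock gene higher, and 3 leukocyte markers lower and 2 higher.

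**Figure D3:**
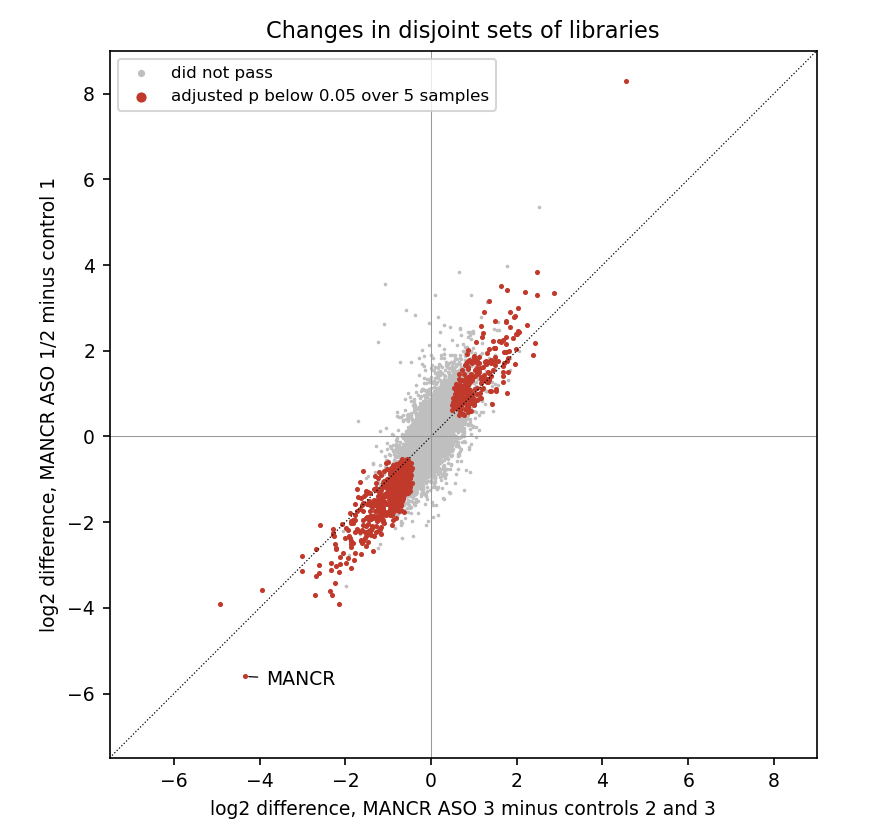
Log2 difference of MANCR ASO sample 1/2 from control 1 (vertical axis) against that of MANCR ASO library 3 from controls 2 and 3 (horizontal axis) for 13503 genes with a mean of at least 50 normalized reads; red genes had an adjusted p below 0.05 over the 5 samples and the dotted line marks equal values. MANCR lies at −5.60 and −4.35, and r across genes is 0.8.

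Genes with long genomic spans fell more often. Among 11439 protein-coding genes with a mean of at least 50 normalized reads, the 497 that fell had a median span of 121.6 kb, the 225 that rose 24.7 kb and the other 10717 genes 33.0 kb. Of 10000 lists matched to the fallers on expression, 0 had a median span as long, and the highest was 44.1 kb. Of 209 genes spanning 400 kb or more, 64 fell (30.6%) and 2 rose, with a median log2 fold change of −0.77; of 3915 genes under 20 kb, 68 fell (1.7%) and 97 rose, with a median of 0.03. For the longest genes the median was −0.86 in MANCR sample 1/2 against control 1 and −0.57 in MANCR library 3 against controls 2 and 3, while control 1 differed from controls 2 and 3 by −0.22. THSD4, IMMP2L, NALF1, GPC6, RAD51B and CAMKMT, all among the named fallers, span 686.4, 899.5, 703.2, 1180.6, 910.4 and 410.6 kb. Among the lists called lower, the median span was 0.4 kb for histones, 12.3 kb for nuclear oxidative phosphorylation, 23.2 kb for cholesterol, 24.8 kb for S phase, 29.7 kb for G2/M and mitosis, 33.8 kb for hypoxia, 47.4 kb for mesenchymal, 48.5 kb for cytokinesis and 65.0 kb for repair genes. It was 87.6 kb for the YAP/TAZ list. Among the long fallers named from these lists, POLA1 spans 303.1 kb, ATM 146.6 kb, ZEB1 211.3 kb, CALD1 226.5 kb, TEAD1 269.9 kb and RBMS3 1435.6 kb.

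**Figure D4:**
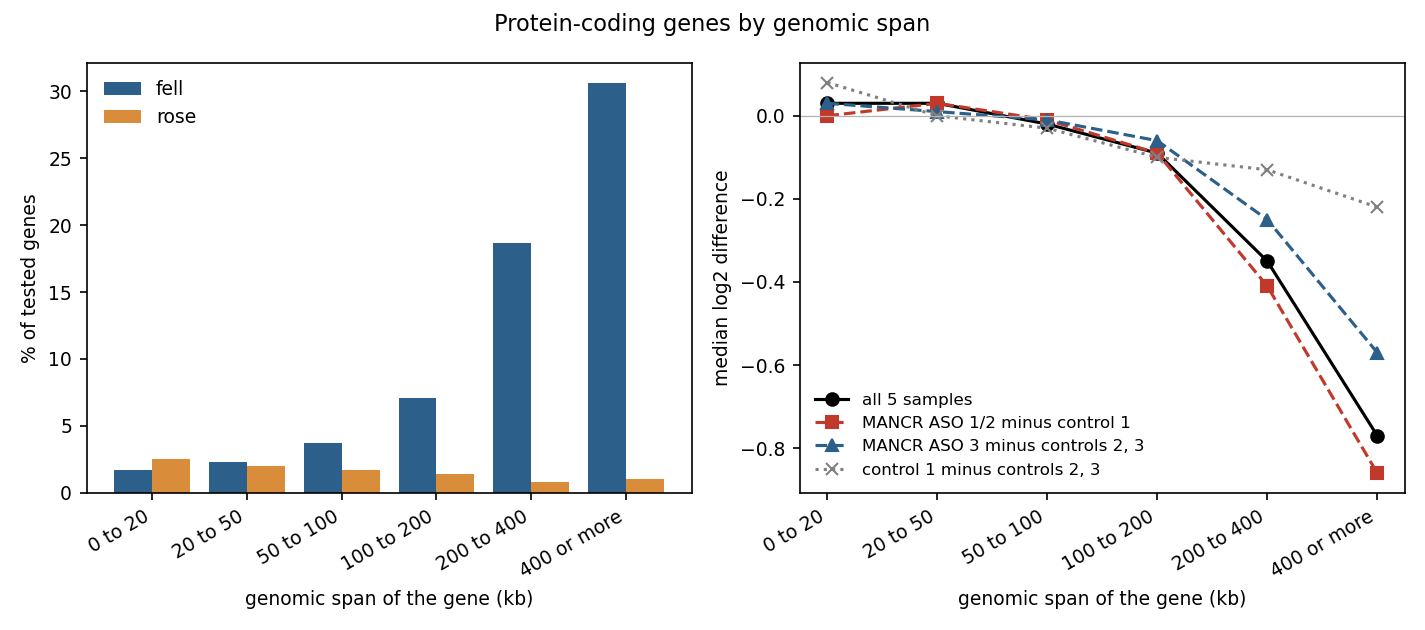
Protein-coding genes by genomic span in kb (horizontal axes): left, the percentage of tested genes that fell (blue) or rose (orange) at an adjusted p below 0.05; right, the median log2 difference over all 5 samples (black), in each disjoint set of libraries (red and blue) and between control 1 and controls 2 and 3 (grey). The share that fell is 1.7% under 20 kb and 30.6% at 400 kb or more.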

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

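The averaging of MANCR ASO libraries 1 and 2 in the main fit was chosen after seeing the data. So were the count over other splits, the fit without MANCR ASO libraries 1 and 2, the library set term and the length and GC correction. The 3 against 3 fit was the main fit of the design fixed beforehand, and the other alternatives were also fixed then. MANCR passed and kept its direction under each setting run (adjusted p up to 0.0297). Among 104 other named genes, 62 were called and 0 reversed under any setting, but 28, 44 and 58 calls were lost without controls 1, 2 and 3, 45 without MANCR ASO libraries 1 and 2, and 31 without the mean-variance trend; with the library set as a term 39 were gained. The 863 changed genes (286 higher, 577 lower) became 335 (120, 215) without the mean-variance trend, 1975 (818, 1157) by DESeq2, 3441 (1432, 2009) as 3 against 3, 95 (6, 89) without MANCR ASO libraries 1 and 2, 4053 (1785, 2268) with the library set as a term, 1319 (482 higher) with length and GC removed, 60 (2, 58) at 0.01 and 2017 (774, 1243) at 0.1. Leaving out 1 library gave 24 to 2257 genes, 2 to 769 higher and 22 to 1488 lower. The cause of these moves was not tested. As the library set was read from the same values, p-values with that term may be too small. The replicate block gave 3771 (1585, 2186). Same-numbered libraries correlated at 0.37, −0.21 and 0.31 in their deviations, and control 2 correlated best with MANCR ASO library 3 (0.31). Because MANCR ASO libraries 1 and 2 count as 1 sample, the value for number 2 cannot test a pairing by number. Whether the numbers pair the libraries stays open. In simulated data 2 of 67 genes changed 1.5-fold were recovered, so many changes of that size may be missed. The simulation had 200 changed genes that varied independently, so the share missed in these data may differ. Of the 15 lists, 0 passed with an estimated correlation (1 at an unadjusted p below 0.05) and 1 by fry. The adjusted p with an estimated correlation was 0.722 for S phase, G2/M, cytokinesis, histone, p53 and repair genes, and by fry 0.0884 for S phase, G2/M and repair, 0.177 for cytokinesis, 0.0515 for histones and 0.302 for p53. Without MANCR ASO libraries 1 and 2 it was 0.403 for p53 targets, and the cholesterol (0.755) and MYC (0.905) lists reversed. Of 10 splits of the 5 samples into 3 and 2, 1 gave 863 genes, the real one. The highest of the others gave 0 by limma (2202 at an unadjusted p below 0.05, against 4163). Each of the others mixes control and MANCR ASO samples, so a difference by ASO widens its spread and makes calls rarer. Also, 10 splits are too few for a share under 0.05.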

Other observations

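All tests below were chosen after the results were seen, as were the window, which was picked by hand from the fallers over all libraries, the limit of 12 bases, the limit of −1.5 for fallers, the stretch lengths of 10 to 14 bases and the library sets. Some genes that share a short stretch with MANCR fell. The stretch TCCACTCACCACTC lies in exon 3 of MANCR (chromosome 10, 4657651 to 4657664, minus strand, GRCh38). Of the other genes tested, 37 hold 12 or 13 consecutive bases of its 14 in a spliced GENCODE 29 transcript. Their median log2 fold change was −0.73; 14 fell and 0 rose, with 37.8% more than 2-fold lower. FAH, a tyrosine catabolism enzyme (−2.10 ± 0.17 SE), the lysosomal galactosylceramidase GALC (−2.05 ± 0.14), the deadenylase subunit PAN2 (−1.75 ± 0.17), the mitochondrial transhydrogenase NNT (−1.80 ± 0.23) and THSD4 (−2.89 ± 0.32) were among them, named after their values were seen. Others did not pass, such as BCL6 (0.27 ± 0.16) and KRT80 (0.26 ± 0.12). With 11 shared bases the median was −0.10 over 58 genes and with 10 bases −0.16 over 378, so the fall did not deepen evenly with match length. None of the fixed cell cycle, histone, repair, epithelial or interferon lists held a tested gene with a match of 12 or 13 bases. Of 17103 tested genes, 37 besides MANCR hold such a match, so few would be likely in these lists. Introns were not searched, so this absence does not show whether the oligonucleotide acted on list members.

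Against chance sharing, the best 11-base stretch of MANCR on the odd chromosomes, CACTCACCACT, was also the best on the others, and was enriched among fallers on the part not used to find it (4 of 14 and 5 of 21 genes, larger p 1.3e-05), although this division was made after the whole had been seen and the best stretches of 12 or 13 bases differed between the parts. As many fallers as those 4 and 5 occurred in 2 and 0 of 10000 lists matched on expression, span and transcript length from the same part (larger share 0.0003), which argues against a greater loss of transcripts from long genes as the reason for these falls. The scan rested on its limits: the lowest Bonferroni p for MANCR and over 50 other lincRNAs was 7.09e-08 and 2.46e-05 for 11 bases, 0.00718 and 0.00143 for 13 and 1.0 and 0.191 for 14, for 10 bases at a limit of −1 it was 2.77e-06 and 1.69e-06, and at a limit of −2 (49 fallers) for 11 bases 0.431 and 0.0275, with 11 lincRNAs as low. A hypothesis is hybridization of the oligonucleotide to these transcripts, which cannot be told apart from other reasons for their fall: its sequence is not given in the labels, and the median of −0.65 in MANCR library 3 against controls 2 and 3 comes from genes already picked with those libraries. A loss secondary to MANCR itself was not tested and stays open.

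The fall of genes with long spans may have a technical source, since control 1 also had lower values for them than controls 2 and 3. That difference was −0.22 at 400 kb or more, against −0.57 in MANCR library 3 and −0.86 in MANCR sample 1/2. At this span a difference of the size seen among controls does not account for the whole fall. The controls do not limit how far the MANCR ASO libraries may differ for technical reasons. At 100 to 200 kb a difference of the size seen among controls may account for the fall. There the median was −0.10 among the controls and −0.09 over the 5 samples. Over all spans, Spearman's rho with span was −0.21 for control 1 minus controls 2 and 3 and −0.18 for the log2 fold change. Removing each library's trend on transcript length and GC content left −0.71 of −0.77 at 400 kb or more. This argues against that trend as the whole source. Hybridization within introns cannot be told apart from other causes, because introns were not searched: the 207 genes of this span without a 12-base match in spliced transcripts had a median of −0.77. A response of long genes to loss of MANCR also stays open, as untested.

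The departure of control 1 and MANCR sample 1/2 from the other libraries outlasted removal of the trend on transcript length and GC content. The correlation of 0.55 stayed at 0.49, which argues against that trend as the whole source. A shared batch or a shared state of the cultures cannot be told apart, because the labels name neither. With the set, which was read from the same values, as a term 4053 genes changed. No biological explanation was tested for it.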
